A study of Mus musculus with 55 samples.

How the data were processed

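RNA-seq libraries had been made from infarcted left ventricle of C57BL/6J mice, with poly(A) selection and a kit that keeps strand, per the labels' protocols. The 55 libraries fall into 6 groups by the sample titles, which give the day after infarction and the diabetic state. The series' design text names day 7 only, so day 28 rests on the titles. The day 7 and day 28 libraries belong to separate sequencing projects, per the library names, so day and project cannot be told apart. The labels do not say whether replicates are separate animals, so every p-value measures the spread between these libraries, which may be in part technical.

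The authors deposited a table of raw counts per Ensembl gene for each day. Per the submitters' processing notes, the genome build was mm39 and DESeq2 was among the tools. The column names at day 28 carry the suffix of a coordinate-sorted alignment file, per the file headers. The aligner, the counting tool, the strand setting and the annotation are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be separated, so antisense transcripts are reported as uncertain. The same holds for genes with near-identical copies, such as immunoglobulin segments, haemoglobin genes, and the Oas1, Ifi200, Slfn, Ly6 and class II families. Of the counts between 1 and 49, 76.4 percent were even at day 7 and 75.2 percent at day 28, as if both mates of most read pairs had been counted. Counting error is then larger than the totals imply, and the tests take the spread from the libraries, not from the counts.

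The deposited counts were used as they stood. All columns matched 1 sample each. The day 7 counts cover 56941 genes and the day 28 counts 57186, with 56867 in both. Gene symbols came from a reference annotation of another build (GENCODE M21, GRCm38) by Ensembl identifier, so no coordinates are given. It paired 51948 identifiers at day 7 and 51880 at day 28 with a symbol, and these genes held 99.34 and 99.58 percent of the counts. Pairs of libraries within a group were compared with a chi-square test over genes with at least 50 counts. The lowest value per gene was 17.6 at day 7 and 25 at day 28, so no library was a repeat of another within sampling noise.

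Differential expression was tested in R 4.3.3 with edgeR 4.0.16 on the raw counts: TMM scaling, the default low-count filter (filterByExpr, minimum count 10 and total 15), glmQLFit and glmQLFTest, with Benjamini-Hochberg adjusted p at or under 0.05 taken as a call. The 3 groups of a day were fitted together, and each pair of groups was compared. A second fit of all 6 groups gave the difference between the diabetic effects at day 28 and day 7, and the change with time in non-diabetic tissue. Adjusted p-values of single genes are from edgeR throughout. Fold changes are log2 values of the first group over the second, with a standard error (SE) equal to their size divided by the square root of the F statistic. Levels are log2 CPM (counts scaled to library size) with a prior count of 2. The number of libraries that show a direction counts those of the first group on that side of the second group's mean log2 CPM.

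Gene lists (53, covering metabolism, signalling, inflammation, matrix and the cell types infarct tissue can hold) were fixed before the data were examined, as were the tests and most alternatives. A list with at least 3 tested members was tested with fry from limma 3.58.1, adjusted over the lists of a comparison. This test asks whether the genes of a list move on balance one way and does not compare the list with other genes. Each list is also given with the number of members called over all genes and the number called when adjusted over the list alone, and with the adjusted p of camera with an estimated correlation between members. Genes are named by a rule fixed before the data were examined. It takes the 6 largest called changes in each direction for a diabetic against a non-diabetic group and 4 for other comparisons, among genes with a mean log2 CPM of at least 1 and a gene name. It adds up to 3 members with the smallest p of each list that passes, in the direction of the list, and 14 fixed genes, among them Pdk4, Angptl4, Cpt1a, Slc2a4, Hk2, Il1b, S100a8, Mrc1, Spp1, Col1a1, Postn, Myh6 and Nppa. Results for some genes chosen by this rule are not reported here.

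The alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE scaling, no low-count filter, only the groups compared in the fit, the replicate number as a block, the cardiomyocyte list as a covariate, each library left out in turn, and sums of libraries of a group that share the first number of their library name. The labels do not say what that number is. Alternatives chosen after the data were seen are named in the closing section. The overlap between both diabetic comparisons of a day, which share controls, was set beside 50 simulations of unchanged groups and 10 splits of the controls. Same-numbered libraries of different groups did not deviate together, so pairing is not established and the fits carry no block.

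The steps were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. For type 1 diabetic against non-diabetic at day 7, over 17944 genes, the test recovered 43.3 percent of genes changed 1.5-fold, 83.6 percent changed 2-fold and 92.4 percent changed 4-fold, with 4.58 percent false calls. For the same comparison at day 28, over 18725 genes, the shares were 50.7, 67.2 and 93.9 percent, with 4.73 percent false calls. For the change of the type 1 effect between days they were 31.3, 52.2 and 75.8 percent, with 6.19 percent false calls.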

Results

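The series measured RNA in infarcted left ventricle of C57BL/6J mice with and without diabetes, 7 or 28 days after a coronary artery had been tied off, by the sample titles (the design text names day 7 only). Its title asks how immune and metabolic gene expression differ between type 1 and type 2 diabetes in healing hearts. At day 7 there were 8 non-diabetic, 8 type 1 diabetic and 8 type 2 diabetic libraries, and at day 28 there were 11, 10 and 10. The names of type 1 libraries carry hi STZ and those of type 2 lo STZ HFFD, so treatments that differ in more than the type of diabetes are not separated from it. Library totals at day 7 ran from 10.8 to 46.8 M (mega) counts in non-diabetic, 31.3 to 51.2 M in type 1 and 30.8 to 48.2 M in type 2 tissue. At day 28 they ran from 58.0 to 84.4, 57.4 to 89.6 and 48.1 to 92.9 M.

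Tissue makeup varied between libraries. At day 7 the mean log2 CPM of 20 cardiomyocyte markers was 9.12 ± 0.58 (SD, n = 8) in non-diabetic, 8.1 ± 1.24 (n = 8) in type 1 and 8.84 ± 0.79 (n = 8) in type 2 tissue, and at day 28 it was 10.86 ± 0.32 (n = 11), 10.62 ± 0.27 (n = 10) and 10.49 ± 0.69 (n = 10). Type 1 replicate 4 at day 7 stood apart: it had the lowest cardiomyocyte mean (5.74) of its group, with Adipoq of adipocytes at a log2 CPM of 6.62 and Ighm of B cells at 11.86. Type 2 replicate 4 at day 28 had Ighm at 12.73 and the lowest mitochondrial share of its group (6.5 percent). The non-diabetic share of mitochondrial counts was 5.44 ± 1.855 percent (SD, n = 8) at day 7 and 17.3 ± 2.86 percent (n = 11) at day 28.

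Type 1 diabetic against non-diabetic tissue at day 7 asks how type 1 diabetes alters the early healing infarct. Type 1 infarcts had higher levels of neutrophil, monocyte and macrophage genes and lower levels of matrix genes (n = 8 against 8). S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, rose by 2.56 (SE 0.624) and 2.68 (SE 0.653) log2 units, and Ccl2, which draws in monocytes, rose by 1.73 (SE 0.302). Eln, which encodes elastin, fell by 2.11 (SE 0.312), and all 8 type 1 libraries lay below every non-diabetic library. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2016 genes rose and 2071 fell of 18165, and 21 of 52 gene lists passed, 0 of them in camera with an estimated correlation.

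Inflammatory and myeloid lists rose at day 7 in type 1 tissue. Of 21 cytokines and chemokines 15 rose, 15 when adjusted over the list alone (median log2 change 1.09, fry adjusted p = 0.00263), among them the monocyte attractants Ccl2 (adjusted p = 0.000448), Ccl7 (1.97) and Ccl12 (1.09), each higher in 8 of 8 libraries. Il1b, which encodes interleukin-1 beta, rose by 1.21 (SE 0.407, adjusted p = 0.0337, 7 of 8 libraries), and this call was lost without any of 4 single libraries, the smallest value being 0.96 without type 1 replicate 7 (adjusted p = 0.0976). Among 14 neutrophil markers 10 rose, 12 over the list alone with 1 fall (median 1.70, fry adjusted p = 0.00795), with Cxcr2 at 2.44, Mmp8 at 1.45 and Clec4e at 1.43. Retnlg rose by 3.02 (SE 0.715, adjusted p = 0.00416, 7 of 8 libraries). Of 14 monocyte markers 10 rose, 10 over the list alone with 1 fall (median 0.69, fry adjusted p = 0.000209), with Ly6c2 at 1.52 and Ifitm6 at 2.07. With an estimated correlation these 3 lists had an adjusted p of 0.311, 0.346 and 0.263. Without type 1 replicate 4, Retnlg was at 1.76, S100a8 at 1.82 and S100a9 at 1.94, with adjusted p of 0.0178, 0.0158 and 0.0151. Without non-diabetic replicate 5, S100a8 and S100a9 were at 3.23 and 3.35.

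Macrophage genes moved the same way. Of 15 macrophage markers 8 rose, 11 over the list alone (median 0.28, fry adjusted p = 0.00263), with the Fc receptor Fcgr1 at 0.85 and Aif1 at 0.65. Of 11 tissue-resident macrophage markers 6 rose and 1 fell, 8 and 1 over the list alone (median 1.10, fry adjusted p = 0.00121), with the folate receptor Folr2 at 1.19 and Pf4 at 1.48. Of 19 reparative macrophage genes 11 rose and 1 fell, both counts the same over the list alone (median 0.70, fry adjusted p = 0.00337). Mrc1, a mannose receptor, rose by 1.11 (SE 0.174, adjusted p = 0.000204, 8 of 8 libraries) and Spp1, which encodes osteopontin, by 0.79 (SE 0.212, adjusted p = 0.0097, 7 of 8). The scavenger receptor Msr1 rose by 1.19. The 3 macrophage lists had an adjusted p of 0.311 each with an estimated correlation.

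Matrix and mesenchymal genes fell. Of 18 collagens 11 fell, 12 over the list alone (median −0.42, fry adjusted p = 0.00197), with Col1a1 at −0.74 (SE 0.152, adjusted p = 0.00151, 8 of 8 libraries), Col6a1 at −0.59 and Col16a1 at −0.90. Of 24 matrix and crosslinking genes 10 fell and 2 rose, 12 and 2 over the list alone (median −0.32, fry adjusted p = 0.00197), with the microfibril protein Mfap4 at −1.16 and Fbln1 at −1.45. Late scar fibroblast markers fell in 10 of 11, by either count (median −1.31, fry adjusted p = 0.000209), with Comp, a cartilage matrix protein, at −1.88 (SE 0.27, adjusted p = 0.000133, 8 of 8 libraries) and Prelp at −1.31. Myofibroblast markers fell in 6 of 12, 7 over the list alone (median −0.45, fry adjusted p = 0.00915), with Cthrc1 at −0.69, Fn1 at −0.52 and Ltbp2 at −0.51. Postn, which encodes periostin, fell by 0.59 (SE 0.17, adjusted p = 0.0143, 7 of 8 libraries). With an estimated correlation these 4 lists had an adjusted p of 0.311, 0.311, 0.263 and 0.358. Of 13 fibroblast markers 5 fell and 1 rose, 6 and 2 over the list alone (median −0.16, fry adjusted p = 0.00571), with Smoc2 at −0.75, Pi16 at −1.03 and Gsn at −0.49, and of 11 mural cell markers 5 fell by either count (median −0.38, fry adjusted p = 0.00184), with Notch3 at −0.64, Myh11 at −0.50 and Pdgfrb at −0.49. These 2 lists had an adjusted p of 0.347 and 0.311 with an estimated correlation.

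The insulin list fell, and glycolysis, pentose and NRF2 lists rose. Of 17 insulin signalling and FoxO target genes 7 fell, 10 over the list alone (median −0.20, fry adjusted p = 0.000209, adjusted p = 0.263 with an estimated correlation), with the insulin receptor substrate Irs1 at −0.81, Foxo3 at −0.44 and Sesn3 at −0.43. Slc2a4, which encodes the insulin-responsive glucose transporter, fell by 1.28 (SE 0.345, adjusted p = 0.0101, 8 of 8 libraries), and was at −0.58 with cardiomyocyte markers as a covariate (adjusted p = 0.0118). Of 18 glycolysis genes 7 rose and 1 fell, 8 and 1 over the list alone (median 0.24, fry adjusted p = 0.0347, adjusted p = 0.514 with an estimated correlation), led by Hk3 (0.89), Pgam1 (0.47) and Pkm (0.39). Of 7 pentose phosphate genes 3 rose by either count, G6pdx (0.55), Taldo1 (0.35) and Pgd (0.32), and of 14 NRF2 target genes 8 rose and 1 fell, 11 and 1 over the list alone, with the cystine carrier Slc7a11 at 1.75 (SE 0.363, adjusted p = 0.00168, 8 of 8), Srxn1 at 0.68 and Gclc at 0.63. Their medians were 0.15 and 0.43, with fry adjusted p of 0.00291 and 0.00197 and an adjusted p of 0.311 each with an estimated correlation. Angptl4, an inhibitor of lipoprotein lipase, rose by 1.13 (SE 0.241, adjusted p = 0.00205, 8 of 8 libraries), while Pdk4 (0.65, SE 0.344, adjusted p = 0.182), Cpt1a (0.16) and Hk2 (0.16) did not pass.

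Lists of lipid and ketone metabolism also passed. Of 19 lipid handling and LXR target genes 6 rose, 7 with 1 fall over the list alone (median 0.13, fry adjusted p = 0.0397, adjusted p = 0.531 with an estimated correlation), among them the fatty acid carrier Fabp5 (0.70). Apoc1 was at 2.48 in all libraries and at 1.03 without type 1 replicate 4, where it no longer passed (adjusted p = 0.0614). Of 7 ketone body genes 1 fell, 0 over the list alone (median −0.27, fry adjusted p = 0.0197, adjusted p = 0.385 with an estimated correlation). That gene was Bdh1, a ketone dehydrogenase, at −1.13 (SE 0.397, adjusted p = 0.0413, 7 of 8 libraries), which was lost without any of 9 single libraries, the smallest value being −0.96 without non-diabetic replicate 2 (adjusted p = 0.103), and Oxct1 was at −0.50 (adjusted p = 0.12).

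Proliferation, interferon and red cell genes rose too. Of 30 cell cycle genes 28 rose, 30 over the list alone (median 0.60, fry adjusted p = 0.00337), with Aurkb at 0.62, Mcm3 at 0.60 and Rrm2 at 0.72. Of 25 interferon-stimulated genes 15 rose, 16 over the list alone (median 0.45, fry adjusted p = 0.004), with the antiviral protein Mx1 at 0.97, the nucleic acid sensor Zbp1 at 0.80 and Irf7, a regulator of interferon genes, at 0.69. Both lists had an adjusted p of 0.311 with an estimated correlation. Of 8 erythroid markers 6 rose, 8 over the list alone (median 2.28, fry adjusted p = 0.00917, adjusted p = 0.347 with an estimated correlation), with the haemoglobin genes Hbb-bs and Hbb-bt, which share reads, at 2.31 and 2.24. Without type 1 replicate 6, Hbb-bs was at 1.71. Cardiomyocyte markers did not pass as a list (median −0.71, 2 of 20 fell, fry adjusted p = 0.127), and Myh6, the main cardiac myosin, was at −1.56 (SE 0.574, adjusted p = 0.0506). Myh7b fell by 2.34, Dhrs7c by 2.22, Armc2 by 2.07 and Kcnip2 by 2.11. Mhrt (−2.28) fell too but is uncertain, being antisense to a myosin gene. Dhrs7c was at −1.79 without non-diabetic replicate 2 (adjusted p = 0.0754), and Kcnip2 at −1.72 (adjusted p = 0.0822), and Kcnip2 lost its call without any of 4 single libraries.

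The largest fitted rises, in Igkv12-89 (5.03), Ighg2b (4.65), Cyp2e1 (4.52) and Car3 (3.88), rested on type 1 replicate 4, which held 99, 99, 97.5 and 92.4 percent of their type 1 counts. Without it they were at −1.45, −1.96, −0.59 and 0.31, and none passed. Summing libraries that share the first number of their name left 1459 calls, and immune cell covariates left 1903, with the interferon list at 0.30 (fry adjusted p = 0.178). With cardiomyocyte markers as a covariate the neutrophil list was at 1.04 (adjusted p = 0.064), and the lipid (0.10, adjusted p = 0.237) and ketone (−0.02, adjusted p = 0.33) lists did not pass.

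Type 2 diabetic against non-diabetic tissue at day 7 asks the same of type 2 diabetes. Interferon-stimulated genes and genes of T cells and NK cells rose, and collagen genes fell (n = 8 against 8). Irf7 rose 2.62-fold (log2 change 1.39, SE 0.127, adjusted p = 4.17e-07), and all 8 type 2 libraries lay above every non-diabetic library. The NK cell receptor Klrk1 rose by 1.30 (SE 0.221), and Eln fell by 1.31 (SE 0.305). The same edgeR test called 700 genes up and 636 down of 18165, and 14 of 52 lists passed, 2 of them in camera.

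Of 25 interferon-stimulated genes 24 rose, 25 over the list alone (median 0.98, fry adjusted p = 5.49e-07), and this held with an estimated correlation (adjusted p = 0.0142). Beside Irf7, Ifi27l2a rose by 1.29 and Oas2, an activator of RNA degradation, by 1.24 (SE 0.133), both in 8 of 8 libraries. Oas1g (1.86), Ifi213 (1.65), Ly6c2 (1.90), Slfn4 (2.36) and Ms4a4c (1.80) were among the largest rises, and reads of these genes can come from close paralogs. The mean log2 CPM of the list was 4.63 ± 0.22 (SD, n = 8) in non-diabetic, 5.09 ± 0.25 in type 1 and 5.63 ± 0.2 in type 2 tissue, and the lowest type 2 library (5.39) lay above the highest non-diabetic library (4.97).

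**Figure D1:**
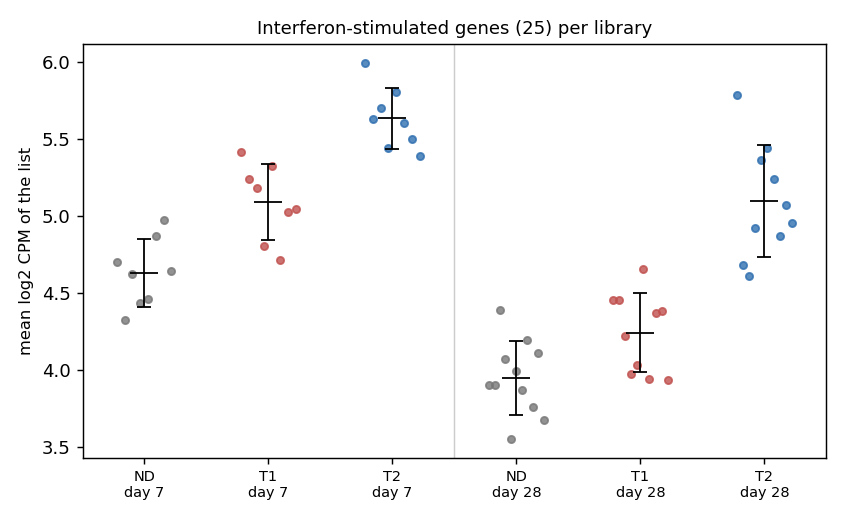
Mean log2 CPM of 25 interferon-stimulated genes in each library (points), by diabetic state and day, with the group mean and SD (bars). Type 2 libraries at day 7 ran from 5.39 to 5.99 against 4.32 to 4.97 in non-diabetic libraries, and at day 28 from 4.61 to 5.78 against 3.55 to 4.39.

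T and NK cell genes rose too. Of 12 NK cell markers 10 rose, 11 over the list alone (median 1.31, fry adjusted p = 2.31e-05, adjusted p = 0.0337 with an estimated correlation), with Klrb1c at 1.51 and the chemokine Ccl5 at 1.03. Of 18 T cell markers 10 rose, 14 over the list alone (median 0.88, fry adjusted p = 0.00054, adjusted p = 0.118 with an estimated correlation), with the signalling kinase Lck (1.08) and the surface protein Cd6 (1.20) higher in 8 of 8 libraries. Monocyte markers rose in 5 of 14 and fell in 1, 6 and 1 over the list alone (median 0.60), and macrophage markers rose in 5 of 15, 12 over the list alone (median 0.34), both with a fry adjusted p of 0.0021 and an adjusted p of 0.181 with an estimated correlation. Plac8 (1.18), Itgal (0.84), Fcgr1 (0.78) and Aif1 (0.69) led them. Class II antigen presentation rose in 2 of 10, 7 over the list alone (median 0.50, fry adjusted p = 0.0199, adjusted p = 0.242 with an estimated correlation), with the protease Ctss at 0.57 and H2-DMb1 at 0.44, a call lost without any of 18 single libraries. Complement rose in 8 of 17, 9 with 1 fall over the list alone (median 0.28, fry adjusted p = 0.0154, adjusted p = 0.206 with an estimated correlation), with Cfb at 1.36, Cfp at 0.69 and C1qa at 0.42. Mrc1 (0.12) and S100a8 (0.34) did not pass, and neutrophil markers did not pass as a list (median 0.53, fry adjusted p = 0.373).

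Matrix genes fell. Of 18 collagens 6 fell, 11 over the list alone (median −0.38, fry adjusted p = 0.00681), with Col5a1 at −0.52, Col5a3 at −0.49 and Col16a1 at −0.49. Col1a1 was at −0.48 (SE 0.151, adjusted p = 0.0508) and did not pass. Matrix and crosslinking genes fell in 9 of 24, 13 with 1 rise over the list alone (median −0.33, fry adjusted p = 0.00874), with Loxl1 at −0.54 and Mfap5 at −0.44. Fibroblast markers fell in 3 of 13 and rose in 1, 8 and 1 over the list alone (median −0.20, fry adjusted p = 0.00681), with Gsn at −0.60, Smoc2 at −0.53 and Pi16 at −0.86. Late scar fibroblast markers fell in 5 of 11, 7 over the list alone (median −0.78, fry adjusted p = 0.0128), with Cilp at −1.09, Comp at −0.99 and Mfap4 at −0.63. Each of these 4 lists had an adjusted p of 0.206 with an estimated correlation. Comp was lost without any of 5 single libraries and Mfap4 without any of 8, at −0.87 and −0.55 without type 2 replicate 1 (adjusted p = 0.051 and 0.0719). Other falls were in Islr2 (−1.34), Rtl3 (−1.32), the proline carrier Slc6a7 (−1.31), Adamts16 (−1.25) and the uncertain antisense transcript Atcayos (−1.21, lost without any of 11 single libraries, at −0.91 without non-diabetic replicate 5).

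Lipid handling, stress and cell cycle lists rose. Of 19 lipid handling and LXR target genes 3 rose, 9 over the list alone (median 0.25, fry adjusted p = 0.00681, adjusted p = 0.206 with an estimated correlation): the cholesterol exporters Abca1 (0.56) and Abcg1 (0.52) and Soat1 (0.30), which esterifies cholesterol. Angptl4 rose by 1.22 (SE 0.241, adjusted p = 0.00279) and Pdk4, a brake on glucose oxidation, by 1.19 (SE 0.347, adjusted p = 0.0369), each in 8 of 8 libraries. The Pdk4 call was lost without any of 8 single libraries, the smallest value being 0.99 without type 2 replicate 8 (adjusted p = 0.0818). Of 17 unfolded protein response genes 1 rose, Asns (0.67), and 6 over the list alone (median 0.32, fry adjusted p = 0.00874, adjusted p = 0.206 with an estimated correlation), with Chac1 at 0.64 and Calr at 0.32. Cell cycle genes rose in 9 of 30, 30 over the list alone (median 0.46, fry adjusted p = 0.0199, adjusted p = 0.264 with an estimated correlation), with Cenpe at 0.65, Aurkb at 0.48 and Mcm3 at 0.41. Alox15, a lipid oxidase, rose by 3.15 (SE 0.707, adjusted p = 0.00796, 7 of 8 libraries) and was at 2.32 without type 2 replicate 3 (adjusted p = 0.0323). Cpt1a (0.17) and Slc2a4 (−0.52) did not pass.

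The count fell to 738 without type 2 replicate 3, to 823 with no low-count filter and to 176 on summed libraries. Of those 176 genes 167 rose and 9 fell, so nearly all falls, unlike part of the rises, lost their calls on sums. With immune cell covariates 0 genes passed in edgeR, 2321 at an unadjusted p under 0.05, against 1901 in DESeq2 and 1941 in limma-voom without covariates, the interferon list was at 0.57 (fry adjusted p = 0.111), and class II genes turned to −0.848 (adjusted p = 0.111) and H2-DMb1 to −0.56.

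Type 1 against type 2 diabetic tissue at day 7 asks directly how the types differ, the question of the title. Type 1 tissue had lower levels of interferon-stimulated and NK cell genes and higher levels of tissue-resident macrophage and cholesterol synthesis genes (n = 8 against 8). Ifi44, an interferon-stimulated gene, was lower by 1.24 log2 units (log2 change −1.24, SE 0.172, adjusted p = 0.000497) and the macrophage transglutaminase F13a1 was higher by 1.66 (SE 0.282, adjusted p = 0.00382), in both cases with all 8 libraries beyond every type 2 library. The edgeR test called 275 genes higher and 217 lower in type 1 tissue of 18165, and 8 of 52 lists passed, 0 of them in camera.

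Of 25 interferon-stimulated genes 15 were lower, 21 over the list alone (median −0.56, fry adjusted p = 0.00132), with Oas2 at −0.79 and Bst2, which tethers virions, at −0.69, and Oas1g (uncertain) at −1.16. Of 12 NK cell markers 5 were lower, 9 over the list alone (median −0.88, fry adjusted p = 0.00132), with the transcription factor Eomes at −1.16, Nkg7 at −0.92 and Ccl5 at −0.88. Both lists had an adjusted p of 0.211 with an estimated correlation. No T cell marker of 18 passed over all genes and 9 were lower over the list alone (median −0.48, fry adjusted p = 0.0209, adjusted p = 0.35 with an estimated correlation), with Cd3e at −0.98, Cd3d at −0.87 and Cd8a at −0.71. Class II genes were lower in 4 of 10, 7 over the list alone (median −0.53, fry adjusted p = 0.0209, adjusted p = 0.342 with an estimated correlation), with Cd74 at −1.01 and the related H2-Eb1 and H2-Ab1 at −1.01 and −0.97.

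Tissue-resident macrophage markers were higher in 5 of 11, 6 over the list alone (median 0.99, fry adjusted p = 0.00562, adjusted p = 0.264 with an estimated correlation), with Mrc1 at 0.99 (SE 0.174, adjusted p = 0.00472, 8 of 8 libraries) and Pf4 at 1.11. Cholesterol and fatty acid synthesis genes were higher in 7 of 23, 13 over the list alone (median 0.38, fry adjusted p = 0.00657, adjusted p = 0.268 with an estimated correlation), with Lss at 0.66 and Hmgcs1 at 0.50. NRF2 target genes were higher in 3 of 14, 7 over the list alone (median 0.40), with Gsta4 at 0.87, Srxn1 at 0.66 and Gclc at 0.57. Insulin signalling and FoxO targets were lower in 2 of 17, 3 over the list alone (median −0.11), with Sesn3 at −0.32 and Fbxo32, a muscle ubiquitin ligase, at −0.57, and Foxo3 at −0.29 without passing. These 2 lists shared a fry adjusted p of 0.0209 and an adjusted p of 0.342 with an estimated correlation. Sprr2g (3.68) and Crct1 (2.63), which belong to epidermal barrier gene families, were higher, and Matn4 (−1.36) and Papln (−1.23) of the matrix were lower. Papln, Fbxo32 and Sesn3 lost their calls without any of 15, 17 and 12 single libraries.

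S100a8 was higher by 2.22 (SE 0.612, adjusted p = 0.0485, 7 of 8 libraries), and the call was lost without any of 15 single libraries, the smallest value being 1.48 without type 1 replicate 4 (adjusted p = 0.122). Neutrophil markers did not pass as a list (8 of 14 over the list alone, median 1.5, fry adjusted p = 0.125), nor did collagens (median −0.05, fry adjusted p = 0.712). Cyp2e1 (7.07) and Ighg2b (5.87) rested on type 1 replicate 4 and were at 2.02 (adjusted p = 0.47) and −0.49 without it. On summed libraries 0 genes passed in edgeR, with 2040 at an unadjusted p under 0.05, against 1040 in DESeq2 and 2927 in limma-voom on single libraries. Immune cell covariates left 4 calls, and leaving out single libraries gave from 157 (type 1 replicate 6) to 1112 (non-diabetic replicate 5).

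Type 1 diabetic against non-diabetic tissue at day 28 asks how type 1 diabetes alters the formed scar and the remaining muscle in the sample. PPAR target, glucocorticoid-responsive and immediate early genes rose (n = 10 against 11). Angptl4 rose 5.25-fold (log2 change 2.39, SE 0.238, adjusted p = 2.37e-07), Pdk4 3.73-fold (1.90, SE 0.216, adjusted p = 2.14e-06) and Cpt1a, which admits fatty acids to mitochondria, 1.7-fold (0.77, SE 0.08, adjusted p = 5.41e-07), and for all 3 genes each of the 10 type 1 libraries lay above every non-diabetic library. The edgeR test called 492 genes up and 267 down of 18901, and 8 of 53 lists passed, 0 of them in camera. The fatty acid oxidation list did not pass (median 0.04, fry adjusted p = 0.809).

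**Figure D2:**
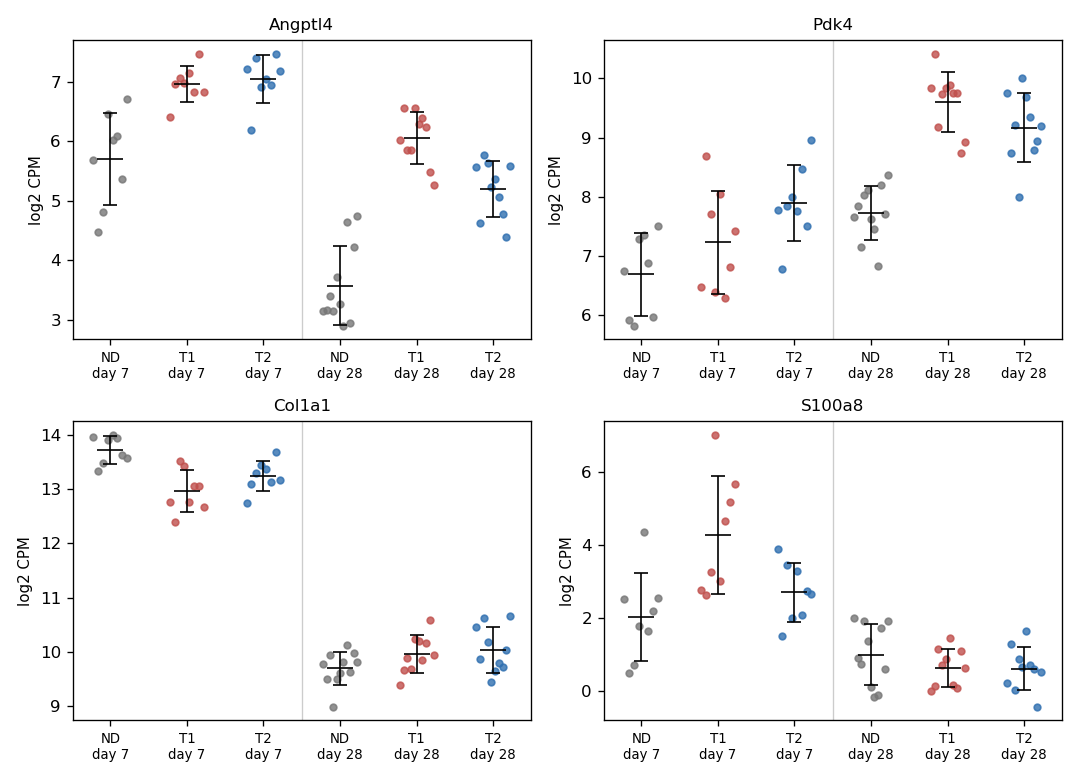
Log2 CPM of Angptl4, Pdk4, Col1a1 and S100a8 in each library (points), by diabetic state and day, with the group mean and SD (bars). At day 28 all 10 type 1 libraries lay above every non-diabetic library for Angptl4 and Pdk4, and at day 7 Col1a1 was lower and S100a8 higher in type 1 tissue.

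Of 23 PPAR target genes 8 rose, 12 with 1 fall over the list alone (median 0.31, fry adjusted p = 0.0203). Glucocorticoid-responsive genes rose in 9 of 16, 11 over the list alone (median 0.66), with the kinase Sgk1 at 0.81 (SE 0.112, adjusted p = 4.97e-05, 10 of 10 libraries), Per1 at 1.03 and the phosphatase Dusp1 at 0.64, and immediate early genes rose in 8 of 18, 11 over the list alone (median 0.58), with Nr4a1 at 1.51, Atf3 at 1.68 and Zfp36 at 0.56. Both also had a fry adjusted p of 0.0203, and all 3 lists had an adjusted p of 0.435 with an estimated correlation. Nr4a3, a nuclear receptor induced by signalling, rose by 1.77 (SE 0.239), Fosb by 1.65 (9 of 10 libraries) and Hif3a, a hypoxia-inducible factor, by 1.70. The circadian list rose in 2 of 16 by either count, Per1 and Per2 (0.92), with Cry2 at 0.20 (median 0.04, fry adjusted p = 0.0312, adjusted p = 0.435 with an estimated correlation).

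Cholesterol and fatty acid synthesis genes fell in 3 of 23, 9 over the list alone (median −0.25, fry adjusted p = 0.0322, adjusted p = 0.435 with an estimated correlation), with the desaturase Scd2 at −0.80, Hmgcs1 at −0.39 and Mvk at −0.36. Bdh1 fell by 1.17 (SE 0.222, 10 of 10 libraries), as did Uts2r (−1.45), the melanin synthesis enzyme Dct (−1.33), the endothelial proteoglycan Esm1 (−1.22) and Chad (−1.21) of cartilage matrix. Cell cycle genes rose in 4 of 30, 13 over the list alone (median 0.30, fry adjusted p = 0.0496, adjusted p = 0.504 with an estimated correlation), with Rrm2 at 0.54, Cdk1 at 0.48 and Prc1 at 0.41. Schwann cell markers rose in 1 of 8 by either count, Gfra3 (0.77), with Sox10 at 0.43 (median 0.27, fry adjusted p = 0.032, adjusted p = 0.435 with an estimated correlation). NRF2 targets passed as a list with 0 of 14 members passing by either count (median 0.13, fry adjusted p = 0.0455, adjusted p = 0.504 with an estimated correlation), with Slc7a11 at 0.93 (adjusted p = 0.0689), Hmox1 at 0.41 and Gsr at 0.17.

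Postn rose by 0.45 (SE 0.12, adjusted p = 0.0279, 10 of 10 libraries) and was lost without any of 6 single libraries, the smallest value being 0.41. Cdk1, Prc1 and Gfra3 lost their calls without any of 13, 15 and 15 single libraries. Col1a1 (0.28), Myh6 (−0.75), Slc2a4 (−0.44), Nppa (0.42) and S100a8 (−0.50) did not pass. Igkv9-120 (−5.96) rested on non-diabetic replicate 6, which held 97.6 percent of the non-diabetic counts, and was at −0.78 without it (adjusted p = 0.676). On summed libraries 6 genes passed and 0 of the 8 lists did, and with the replicate number as a block 333 genes passed. Leaving out single libraries gave from 443 genes (type 1 replicate 5) to 1163 (type 2 replicate 4).

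Type 2 diabetic against non-diabetic tissue at day 28 asks the same of type 2. Interferon-stimulated, T cell, NK cell and cell cycle genes rose (n = 10 against 11). Irf7 rose 3.98-fold (log2 change 1.99, SE 0.158, adjusted p = 8.35e-10), and each of the 10 type 2 libraries lay above every non-diabetic library. Plac8, a myeloid gene, rose by 1.99 (SE 0.239, adjusted p = 1.17e-06, 10 of 10), and Top2a, a topoisomerase of dividing cells, by 0.96 (SE 0.143). Of 18901 genes, 1362 rose and 662 fell in the edgeR test, and 12 of 53 lists passed, 1 of them in camera.

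All 25 interferon-stimulated genes rose, by either count (median 1.12, fry adjusted p = 5.25e-08, adjusted p = 0.0316 with an estimated correlation), with Bst2 at 1.12 and Oas1a, which has close paralogs, at 1.37. The list's mean log2 CPM was 3.95 ± 0.24 (SD, n = 11) in non-diabetic, 4.24 ± 0.26 (n = 10) in type 1 and 5.09 ± 0.36 (n = 10) in type 2 tissue. Ifi206 (uncertain) rose by 2.08. T cell markers rose in 16 of 18, 18 over the list alone (median 1.20, fry adjusted p = 0.0102, adjusted p = 0.498 with an estimated correlation), with the receptor constants Trbc1 and Trbc2, which share reads, at 1.37 and 1.46. Foxp3, the regulator of regulatory T cells, was at 2.12 and at 1.04 without type 2 replicate 4 (adjusted p = 0.042). NK cell markers rose in 9 of 12, 10 over the list alone (median 1.04, fry adjusted p = 0.000378, adjusted p = 0.201 with an estimated correlation), with Klre1 at 1.41, the granule protease Gzmb at 1.36 and Klrb1c at 1.32, each in 10 of 10 libraries.

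Myeloid and antigen-presentation genes rose too. Monocyte markers rose in 7 of 14, 9 with 1 fall over the list alone (median 1.06, fry adjusted p = 0.00298, adjusted p = 0.356 with an estimated correlation), with Ly6c2 at 1.57. Class II genes rose in 8 of 10, 9 over the list alone (median 0.85, fry adjusted p = 0.017, adjusted p = 0.515 with an estimated correlation), with Cd74 at 0.95, H2-Aa at 0.91 and Ctss at 0.82. Macrophage markers rose in 5 of 15, 9 over the list alone (median 0.39, fry adjusted p = 0.0343, adjusted p = 0.581 with an estimated correlation), with the endotoxin co-receptor Cd14 at 1.07 and C1qa at 0.51. Complement rose in 6 of 17, 10 over the list alone (median 0.47, fry adjusted p = 0.0443, adjusted p = 0.596 with an estimated correlation), with Cfb at 1.35 and Itgax at 0.85. Dendritic cell markers rose in 3 of 11, 6 over the list alone (median 0.32, fry adjusted p = 0.0264, adjusted p = 0.577 with an estimated correlation), with Clec9a at 0.62, Ccl22 at 0.84 and the homing receptor Ccr7 at 1.16. Ccl22 was at 0.70 without type 2 replicate 9 (adjusted p = 0.0617) and Ccr7 at 0.63 without type 2 replicate 4 (adjusted p = 0.0607), and neither passed there.

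Cell cycle genes rose in 26 of 30, 29 over the list alone (median 0.77, fry adjusted p = 1.57e-05, adjusted p = 0.0985 with an estimated correlation), with Ube2c at 1.00 and Rrm2 at 0.95. Glucocorticoid-responsive genes rose in 10 of 16, 14 over the list alone (median 0.82, fry adjusted p = 0.000291, adjusted p = 0.189 with an estimated correlation), with Sgk1 at 0.81, Cdkn1a at 0.77 and Dusp1 at 0.75. Immediate early genes rose in 6 of 18, 8 over the list alone (median 0.57), with Nr4a1 at 1.24 and Klf2 at 0.51, and lipid handling genes in 4 of 19, 7 over the list alone (median 0.17), with Abcg1 at 0.53, Abca1 at 0.42 and the lysosomal lipase Lipa at 0.32. These 2 lists had a fry adjusted p of 0.0264 and an adjusted p of 0.577 with an estimated correlation. Angptl4 rose by 1.54 (SE 0.232, adjusted p = 3.92e-05), Pdk4 by 1.48 (SE 0.213, adjusted p = 1.99e-05) and Cpt1a by 0.49 (SE 0.08), each in 10 of 10 libraries, while PPAR targets did not pass as a list (6 of 23 rose, median 0.12, fry adjusted p = 0.0744). Falls were led by Uts2r (−1.54), the kinase Hipk2 (−1.32), Slc6a7 (−1.10), Nt5c1a (−1.03), the transferrin receptor Tfrc (−0.98) and Frem2 (−0.96). Tfrc was at −0.78 without non-diabetic replicate 4 (adjusted p = 0.0537). Col1a1 (0.38), Nppa (−0.34) and Myh6 (−0.56) did not pass.

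The rise of Arg1 (3.08), which encodes arginase, rested on type 2 replicate 10, with 85.4 percent of the type 2 counts, and was at 0.20 without it (adjusted p = 0.91), where the acute-phase gene Saa3 went from 2.61 to 2.00 (adjusted p = 0.0961). The immunoglobulin segments Igkv16-104 (4.68), Ighv5-17 (3.58) and Ighv1-39 (3.40) were at −0.13, 1.51 and −0.03 without type 2 replicate 4 and did not pass. Summed libraries left 427 calls and immune cell covariates 782, where the interferon list was at 0.89 and still passed. There class II genes were at −0.058 (adjusted p = 0.386), dendritic markers at 0.056 with fry down (adjusted p = 0.616) and Ccr7 at −0.08, so these rises were lost and turned.

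Type 1 against type 2 diabetic tissue at day 28 asks how the types differ late after infarction. Interferon-stimulated, T cell and NK cell genes were lower and cardiac stress genes higher in type 1 tissue (n = 10 against 10). Irf7 was at −1.23 (SE 0.16, adjusted p = 2.23e-05) and lower in 10 of 10 libraries, and Nppa, a natriuretic peptide of stressed cardiomyocytes, was higher by 0.76 (SE 0.169, adjusted p = 0.00772, 10 of 10). In the edgeR test 224 genes were higher and 383 lower of 18901, and 6 of 53 lists passed, 1 of them in camera.

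Interferon-stimulated genes were lower in 24 of 25, 25 over the list alone (median −0.84, fry adjusted p = 1.68e-05, adjusted p = 0.0218 with an estimated correlation), with Oas1a (uncertain) at −1.05. NK cell markers were lower in 6 of 12, 12 over the list alone (median −1.10, fry adjusted p = 0.00122, adjusted p = 0.0904 with an estimated correlation), with Gzma at −1.27, Nkg7 at −1.27 and Klrb1c at −1.10. T cell markers were lower in 8 of 18, 17 over the list alone (median −1.20), with the checkpoint receptor Ctla4 at −1.42, Cd3e at −1.45 and Cd3g at −1.30, and monocyte markers in 3 of 14, 8 over the list alone (median −0.85), with Plac8 at −1.54, Ly6c2 at −1.72 and Chil3 at −1.43. These 2 lists had a fry adjusted p of 0.0244 and an adjusted p of 0.267 with an estimated correlation. Cd3e and Cd3g varied widely between type 2 libraries, at 2.3 ± 2.5 and 3.8 ± 2.7 CPM (SD, n = 10). Cell cycle genes were lower in 8 of 30, 24 over the list alone (median −0.42, fry adjusted p = 0.0241, adjusted p = 0.267 with an estimated correlation), with Ube2c at −0.73, Kif11 at −0.58 and Nusap1 at −0.46.

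Cardiac stress genes were higher in 3 of 14, 5 over the list alone (median 0.41, fry adjusted p = 0.0241, adjusted p = 0.253 with an estimated correlation): Nppa, the slow myosin Myh7 (0.61) and Uchl1 (0.56). Angptl4 was higher by 0.85 (SE 0.235, adjusted p = 0.04, 10 of 10 libraries), while Pdk4 (0.42) and Cpt1a (0.28, adjusted p = 0.0533) did not pass. Lrrc4b (1.20), the imprinted gene Peg3 (0.92) and Hipk2 (0.87) were higher as well. Myh7, Chil3 and Angptl4 lost their calls without any of 21, 15 and 10 single libraries, and Cd3e without any of 3, at −0.87 without type 2 replicate 4 (adjusted p = 0.105).

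The segments Igkv16-104 (−6.91), Ighv1-22 (−6.58), Ighv1-39 (−6.48) and Igkv4-68 (−5.91) rested on type 2 replicate 4 and were at −2.08, −2.82, −3.05 and −0.81 without it, where none passed. Immune cell covariates left 112 calls, summed libraries 125 and the replicate block 376, and without type 1 replicate 5 there were 372.

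The genes called for both types of diabetes overlapped. At day 7, 917 genes passed for both types in the same direction, 428 up and 489 down, and 0 in opposite directions, where independent calls would give 77.7 and 72.5. Shared controls by themselves link both comparisons. The 50 simulations changed no gene, so their 0 shared genes cannot size that link. With split controls, thus fewer libraries, the mean of 10 splits was 176.9 genes (89 to 301). Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.59, against 0.51 simulated and 0.2 with split controls. At day 28, 362 genes were shared, 242 up and 120 down, with 2 in opposite directions, against 35.5 and 9.35 for independent calls and a mean of 52.5 with split controls. The Pearson correlation there was 0.36, against 0.47 in the simulations without change and 0.1 with split controls. Angptl4 rose for both types on both days. Between days, with separate libraries throughout, 70 genes rose for type 1 on both days (54.2 for independent calls), 47 fell (29.8) and 92 went in opposite directions, while for type 2 these numbers were 356 (51.9), 65 (23.1) and 14.

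The difference between the type 1 effect at day 28 and at day 7 was tested directly in a fit of all 6 groups, which cannot be told apart from a difference between sequencing projects. The effect on matrix genes was higher at day 28 and the effect on myeloid genes lower. The difference was 2.52 for Eln (SE 0.353, adjusted p = 5.31e-06), 2.66 for Matn4 (SE 0.391), 1.01 for Col1a1 (SE 0.219) and −3.07 for S100a8 (SE 0.645, adjusted p = 0.000905). The edgeR test called 1425 genes with a higher and 1123 with a lower effect at day 28 of 20421, and 16 of 53 lists passed, 0 of them in camera.

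Collagens had a higher effect in 9 of 18, 13 over the list alone (median 0.59, fry adjusted p = 0.00161), with Col14a1 and Col16a1 at 1.20 each and Col6a1 at 0.78, as did matrix genes in 13 of 24 with 1 lower (median 0.61, fry adjusted p = 0.00212), with Thbs2 at 1.55 and Mfap4 at 1.47. Myofibroblast markers were higher in 6 of 12, 7 over the list alone (median 0.75, fry adjusted p = 0.00226), with Cthrc1 at 1.46, Postn at 1.02 and Ltbp2 at 0.97. Late scar fibroblast markers were higher in 9 of 11 by either count (median 1.40, fry adjusted p = 3.5e-05, adjusted p = 0.108 with an estimated correlation), with Comp at 2.03 and Fmod at 1.87. The first 3 lists had an adjusted p of 0.235 each with an estimated correlation. Fibroblast markers (median 0.17, 4 of 13 higher and 1 lower, 5 and 2 over the list alone, fry adjusted p = 0.0366, adjusted p = 0.505 with an estimated correlation) included Tcf21 and Pi16 at 0.97 each and Smoc2 at 0.94. Mural markers (median 0.33, 3 of 11 higher, 6 over the list alone, fry adjusted p = 0.0111, adjusted p = 0.352 with an estimated correlation) included Notch3 at 0.98, Myh11 at 0.58 and Mylk at 0.53.

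Tissue-resident macrophage markers had a lower effect at day 28 in 7 of 11 and a higher effect in 1, 8 and 1 over the list alone (median −1.79, fry adjusted p = 0.00109, adjusted p = 0.235 with an estimated correlation), with F13a1 at −2.21, Cbr2 at −2.05 and Pf4 at −1.79. Cytokines were lower in 7 of 22, 8 over the list alone (median −0.82, fry adjusted p = 0.0111, adjusted p = 0.352 with an estimated correlation), with Ccl7 at −2.40, Cxcl5 at −2.21 and Ccl2 at −1.96. Neutrophil markers were lower in 7 of 16, 9 over the list alone (median −1.52, adjusted p = 0.427 with an estimated correlation), with S100a9 at −3.19 and Cxcr2 at −2.38, and monocyte markers in 3 of 14 with 2 higher, 7 and 2 over the list alone (median −0.66, adjusted p = 0.435 with an estimated correlation), with Chil3 at −2.88, Ifitm6 at −2.16 and Ly6c2 at −1.67. Both had a fry adjusted p of 0.0366. Erythroid markers were lower in 6 of 8, 7 over the list alone (median −2.11, fry adjusted p = 0.0322, adjusted p = 0.427 with an estimated correlation), with Hbb-bs and Hbb-bt at −2.12 and −2.16. Mrc1 was at −1.22 and Spp1 at −0.88.

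Metabolic effects also differed between days. Insulin signalling and FoxO targets had a higher effect at day 28 in 6 of 18 by either count (median 0.33, fry adjusted p = 3.5e-05, adjusted p = 0.108 with an estimated correlation), with Irs2 at 1.15, Foxo3 at 0.64 and Sesn3 at 0.48. Cholesterol synthesis was lower in 12 of 23, 16 over the list alone (median −0.47, fry adjusted p = 0.00241, adjusted p = 0.235 with an estimated correlation), with Hmgcs1 at −0.71, Scd2 at −0.67 and Fdps at −0.49. NRF2 targets were lower in 5 of 14, 8 with 1 higher over the list alone (median −0.42, fry adjusted p = 0.0111, adjusted p = 0.352 with an estimated correlation), with Gclc at −0.49 and Prdx1 at −0.46. Circadian genes were higher in 3 of 16, 4 over the list alone (median 0.52, fry adjusted p = 0.00621, adjusted p = 0.352 with an estimated correlation), with Per2 at 1.04, Ciart at 1.01 and Cry2 at 0.63. The pentose phosphate list was lower in 1 of 7 by either count, G6pdx at −0.45 (median −0.20, fry adjusted p = 0.017, adjusted p = 0.363 with an estimated correlation). Angptl4 was at 1.25 (SE 0.343, adjusted p = 0.0106), Pdk4 at 1.23 (SE 0.401, adjusted p = 0.0344) and Cpt1a at 0.58. C1qtnf3 (2.92), Col2a1 (2.77) and Myoc (2.58) were among the largest differences, and Ighv1-66 (−14.09), Igkv4-57 (−11.98), Igkv9-120 (−7.93) and Ighv1-64 (−7.51) came from segments with most counts in 1 or 2 libraries. Ighv1-66 had 0 counts in all 8 non-diabetic libraries at day 7 and 7386 in type 1 replicate 4, so its fitted value is not a measured fold. On summed libraries 423 genes passed.

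For type 2 diabetes the same test called 221 genes with a higher and 87 with a lower effect at day 28, and no list of 53 passed. Fbln7 (1.82, SE 0.323, adjusted p = 0.00183), Spock2 (1.62) and Matn4 (1.49) of the matrix had a higher effect at day 28, as did Col1a1 (0.83, SE 0.219, adjusted p = 0.0363). Hipk2 (−1.86, SE 0.325, adjusted p = 0.00183), the chemokines Cxcl5 (−2.15) and Ccl7 (−1.45) and Esm1 (−1.40) had a lower effect. Collagens had a higher effect in 5 of 18, 12 over the list alone, without passing as a list (median 0.55, fry adjusted p = 0.156), and Angptl4 (0.29) and Pdk4 (0.25) did not pass. The segment Ighg2c (3.87) had 50.1 percent of its type 2 counts at day 28 in replicate 4. On summed libraries 0 genes passed in edgeR, with 1823 at an unadjusted p under 0.05, against 612 in DESeq2 and 429 in limma-voom on single libraries, and the replicate block left 191.

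Non-diabetic tissue at day 28 against day 7 shows change with time, but day, project and cardiomyocyte share are not separated. Matrix, macrophage and cell cycle genes fell and mitochondrial and cardiomyocyte genes rose (n = 11 against 8). Col1a1 fell by 3.71 (SE 0.161, adjusted p = 7.74e-26), Spp1 by 4.28 (SE 0.229) and Birc5, which is needed for cell division, by 2.64 (SE 0.141), while Tnni3, a cardiac troponin, rose by 2.5 (SE 0.349). The edgeR test called 6408 genes up and 6887 down of 20421, and 37 of 53 lists passed. None passed with an estimated correlation (adjusted p from 0.265 to 0.886), so the lists that follow were not set apart from other genes. The cardiomyocyte covariate kept 61.2 percent of gene calls.

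All 18 collagens fell (median −1.75, fry adjusted p = 8.49e-21), with Col11a1 at −4.93 and Col5a1 at −2.88, as did 10 of 12 myofibroblast markers, with 1 rise over the list alone (median −2.45, fry adjusted p = 1.63e-20), with Cthrc1 at −3.84, Ccn4 at −3.64 and Postn at −2.79, and both lists had an adjusted p of 0.265 with an estimated correlation. All 15 macrophage markers fell (median −1.19, fry adjusted p = 5.23e-15), with Cd68 at −2.24 and Ctsb at −1.54, as did all 30 cell cycle genes (median −2.33, fry adjusted p = 1.32e-17), with Cdk1 at −2.54, and both had an adjusted p of 0.312 with an estimated correlation. Matrix proteases fell in 17 of 23 and rose in 2 (median −1.11, fry adjusted p = 1.32e-13), with Mmp14 at −2.44, and reparative macrophage genes fell in 14 of 19 and rose in 2 (median −1.40, fry adjusted p = 1.12e-15), with Gpnmb at −3.77, both at an adjusted p of 0.312 with an estimated correlation. Gsn (3.06), Pi16 (2.23) and the cartilage matrix genes Chad (3.16) and Cilp2 (3.02) rose.

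All 39 nuclear-encoded oxidative phosphorylation genes rose (median 1.60, fry adjusted p = 1.12e-12, adjusted p = 0.312 with an estimated correlation), with Ndufb10 at 1.87, as did all 19 TCA cycle genes (median 1.68, fry adjusted p = 2.08e-12, adjusted p = 0.312 with an estimated correlation), with Mdh2 at 1.75. Fatty acid oxidation rose in 22 of 23 and fell in 1 (median 1.80, fry adjusted p = 1.79e-11, adjusted p = 0.332 with an estimated correlation), with Ech1 at 2.15. All 20 cardiomyocyte markers rose beside them (median 2.03, fry adjusted p = 1.07e-06, adjusted p = 0.58 with an estimated correlation), as did all 13 adipocyte markers (median 5.00, fry adjusted p = 0.000396, adjusted p = 0.697 with an estimated correlation), with Thrsp at 2.85. Counts over each of these lists alone were the same. Nppa (1.61), Nppb (2.00), Slc2a4 (2.01) and Pdk4 (1.29) rose, and Angptl4 (−1.82) and Cpt1a (−0.79) fell. Fibroblast markers rose in 6 of 13 and fell in 5 (median 0.05, mean 0.39, fry up, adjusted p = 4.3e-06, adjusted p = 0.778 with an estimated correlation). For mural markers the median (0.11) and the mean (−0.15) differed in sign, and fry called a fall (adjusted p = 0.00692, adjusted p = 0.886 with an estimated correlation). Myh2 (7.02, SE 1.782) is a skeletal muscle myosin, and skeletal muscle markers did not pass as a list (median 4.04, fry adjusted p = 0.172). Igkv9-120 (7.44) and Ighv1-64 (5.86) had 97.6 and 84.1 percent of their counts at day 28 in replicate 6. Zfp862-ps, Zrsr1, Slc2a4rg-ps and Gpx4-ps2 were listed at 0 in all day 28 libraries, as were 29 genes of at least 1 CPM at day 7 in all, with 0 genes the other way, so no fold is given for them.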

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

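The tests of the interferon, collagen and PPAR patterns were chosen after the data were seen, with their bounds written after the fits had been run but before their values were looked at, while the differences between days had been planned.

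Some libraries lay far from the rest of their group. Of 65 groups of values tested, 7 had such a library, where chance alone gives about 1 in 20. Non-diabetic replicate 4 at day 7 had the lowest total, 10.8 M counts against 34.2 M in the nearest library. Type 2 replicate 1 at day 7 had a collagen mean of 9.7 log2 CPM, with the nearest library at 10.1. Type 2 replicate 4 at day 28 had a cardiomyocyte mean of 8.68, with the nearest at 10.23. The B cell mean was 3.71 in non-diabetic replicate 4 at day 7 (nearest 1.9), 5.9 in type 1 replicate 4 at day 7 (nearest 2.2) and 6.73 in type 2 replicate 4 at day 28 (nearest 3.21). Type 1 replicate 10 at day 28 had the lowest cell cycle mean, 2.07, with the nearest at 2.36.

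Effects of diabetes that differed between days were tested as such in the fit of all 6 groups, with 2548 genes for type 1 and 308 for type 2. For type 1 the median differences of the 16 lists that passed were −0.20 for pentose phosphate, 0.33 for insulin signalling and FoxO targets, −0.47 for cholesterol synthesis, 0.52 for circadian genes, −0.42 for NRF2 targets, −0.82 for cytokines, 0.59 for collagens, 0.61 for matrix proteins, 0.17 for fibroblast, 0.75 for myofibroblast, 1.40 for late scar fibroblast and 0.33 for mural markers, and −1.79, −0.66, −1.52 and −2.11 for tissue-resident macrophage, monocyte, neutrophil and erythroid markers. With camera and an estimated correlation 0 of 53 lists passed for this difference. Among named genes the type 1 difference was 2.92 for C1qtnf3, 2.77 for Col2a1, 2.66 for Matn4, 2.58 for Myoc, 1.25 for Angptl4, 1.23 for Pdk4, 1.02 for Postn, 1.01 for Col1a1, 0.58 for Cpt1a, −0.88 for Spp1, −1.22 for Mrc1 and −3.07 for S100a8. It was −14.09 for Ighv1-66, −11.98 for Igkv4-57, −7.93 for Igkv9-120 and −7.51 for Ighv1-64, resting on type 1 replicate 4 at day 7 for the first 2 (7386 and 15743 counts) and mainly on non-diabetic replicate 6 at day 28 for the others (12986 and 6169). The type 2 difference was 3.87 for Ighg2c, 1.82 for Fbln7, 1.62 for Spock2, 1.49 for Matn4, 0.83 for Col1a1, −1.40 for Esm1, −1.45 for Ccl7, −1.86 for Hipk2 and −2.15 for Cxcl5.

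Interferon-stimulated genes were higher in type 2 than in non-diabetic tissue on both days. All type 2 clusters of libraries sharing a first name number (4 at day 7, 5 at day 28) averaged above every non-diabetic cluster. This argued against origin in 1 cluster. Groups of a day share no number, so a batch difference between them stays open. A larger share of macrophages, T cells and NK cells, whose lists share 0 of 25 genes with the interferon list, was argued against as the whole cause at day 28, where the median stayed at 0.89 from 1.12 with these lists as covariates. At day 7 the median was 0.57, from 0.98, and no longer passed (fry adjusted p = 0.111), so there a larger immune cell share and a stronger response per cell cannot be told apart. A stronger interferon response in type 2 diabetes stays a hypothesis on both days.

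Collagen genes were lower in type 1 than in non-diabetic tissue at day 7, a call lost with an estimated correlation (adjusted p = 0.311). A different share of cardiomyocytes was argued against as the whole cause, since the median was −0.45 with cardiomyocyte markers as a covariate and −0.42 without, and the lists share 0 of 18 genes. The libraries that stand apart were argued against too, with a median of −0.41 when they were left out. Of 13 fibroblast markers 5 were lower and 1 higher (adjusted p = 0.347 with an estimated correlation). A larger immune cell share, fewer fibroblasts, lower collagen output per fibroblast and a different scar stage stay open.

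PPAR target genes were higher in type 1 than in non-diabetic tissue at day 28, a call lost with an estimated correlation (adjusted p = 0.435) and on summed libraries (median 0.42, fry adjusted p = 0.249). A larger share of adipocytes was argued against, since the median was 0.33 with adipocyte markers as a covariate (fry adjusted p = 0.0173) and 0.31 without, and so was a different share of cardiomyocytes (0.41). With immediate early genes as a covariate the median was 0.26 and the list no longer passed (fry adjusted p = 0.0713), while 7 of 23 members still rose. A response to tissue collection and an effect of diabetes on lipid supply to the tissue therefore cannot be told apart from the list alone.

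Other splits of the libraries into groups of the same sizes gave fewer calls than the real groups in each comparison, so that 1 split, the real one, was as large. With 100 splits each, the real count and the highest other were 4087 and 3025 for type 1 against non-diabetic at day 7, 1336 and 1 for type 2, and 492 and 0 for type 1 against type 2. At day 28 they were 759 and 389, 2024 and 82, and 607 and 1. With 40 splits each, they were 2548 and 854 for the type 1 difference between days, 308 and 2 for type 2, and 13295 and 2672 for time. But 100 or 40 splits are too few to exclude chance assignment of single libraries. The splits did not keep libraries that share a first name number together, so they do not cover that structure, and how the splits with 3025, 389, 854 and 2672 calls were composed was not tabulated.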

How the results depend on the processing

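Leaving out the libraries that stand apart, the skeletal muscle and B cell covariates and the immune cell covariates were chosen after the data were seen, and the immune covariates were first set for the interferon list, widened once counts had been seen, narrowed for a time and widened again. Of 447 named gene values, 427 kept direction and call in DESeq2, 413 in limma-voom, 447 with RLE scaling, 413 with no filter, 395 with cardiomyocyte markers as a covariate and 255 on summed libraries. Of 122 list calls, 121 were kept with RLE scaling, 117 without the libraries that stand apart, 96 with the cardiomyocyte covariate, 69 on summed libraries and 4 with an estimated correlation. Of 58 list calls tested with immune covariates 20 were kept, of 26 with skeletal muscle and B cell covariates 26. The cause was not tested, except that sums leave fewer samples and no filter adds genes by construction. Libraries were not left out singly for the differences between days or for time. Simulated 1.5-fold changes were recovered in 31.3 to 52.2 percent of genes and 4-fold changes in 75.8 to 95.5 percent, so small changes were missed. In all day 28 libraries 29 genes of at least 1 CPM at day 7 were at 0, with 0 genes the other way. Differing annotation of the count tables may bear on changes between days.

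On summed libraries the counts in the order type 1, type 2 and type 1 against type 2 were 1459, 176 and 0 at day 7 and 6, 427 and 125 at day 28, with 423 and 0 for the differences between days, and 81 and 5 genes called in the same direction in both types of diabetes. The counts of 0 in edgeR had 2040 and 1823 genes at an unadjusted p under 0.05, and on single libraries DESeq2 gave 1040 and 612 and limma-voom 2927 and 429. With immune covariates the counts were 1903, 0 and 4 at day 7, and 986, 782 and 112 at day 28, the first of these a rise from 759. That 0 had 2321 genes at an unadjusted p under 0.05, and no other tool was run with these covariates. With no filter the counts were 823 and 289 for type 2 and type 1 against type 2 at day 7. They were 440 and 403 for type 1 and type 1 against type 2 at day 28. The type 2 difference between days had 158. Both types shared 521 and 212 genes at days 7 and 28, and type 1 shared 57 between days.

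DESeq2 gave 1171 genes for type 1 and 1004 for type 1 against type 2 at day 28, and limma-voom gave 3025 for type 1 at day 28 and 3907 for its difference between days. With cardiomyocyte markers as a covariate there were 1476 and 1224 genes for type 1 and type 1 against type 2 at day 28. The type 2 difference had 564, and 611 were shared by both types at day 28. With the replicate block these were 333, 376 and 191, the last for the type 2 difference. A fit of only type 1 and type 2 at day 7 gave 983. Without the libraries that stand apart (non-diabetic and type 1 replicate 4 at day 7, type 2 replicate 4 at day 28, and not type 2 replicate 1 at day 7 or type 1 replicate 10 at day 28) there were 740 genes for type 1 against type 2 at day 7, 1163 for type 1 at day 28 and 165 for the type 2 difference. Split controls gave 176.9 and 52.5 shared genes on average. Leaving out single libraries gave 3201 to 5345, 738 to 1975 and 157 to 1112 genes at day 7 and 443 to 1163, 1588 to 2447 and 372 to 717 at day 28.

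Type 2 at day 7 fell to 831 without non-diabetic replicate 2 and to 801, 738 and 791 without type 2 replicates 1, 3 and 5. Type 1 against type 2 at day 7 went to 1112 without non-diabetic replicate 5, to 980, 157, 255 and 195 without type 1 replicates 3, 6, 7 and 8, and to 206, 271, 176 and 267 without type 2 replicates 2, 4, 6 and 8. Type 1 at day 28 went to 443, 498 and 471 without type 1 replicates 5, 6 and 8, and to 1163 without type 2 replicate 4.

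Directions turned in these cases, none of which passed except Myh6 over time. With immune covariates the list medians were −0.043 for lipid handling in type 1 at day 7, −0.848 and −0.058 for class II in type 2 at days 7 and 28, and 0.056 for dendritic markers in type 2 at day 28, where fry turned down. Genes with immune covariates were Atcayos 0.11, Soat1 −0.02, H2-DMb1 −0.56 and Col5a3 0.18 in type 2 at day 7, H2-Eb1 and H2-Ab1 0.02 each, Cyp2e1 −1.78 and Ighg2b −2.35 in type 1 against type 2 at day 7, Ccr7 −0.08, Igkv16-104 −1.87 and Ighv1-39 −0.51 in type 2 at day 28, Igkv12-89 −1.21 in type 1 at day 7 and Igkv4-68 1.10 in type 1 against type 2 at day 28.

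Igkv12-89 in type 1 at day 7 was −1.81 in DESeq2, −0.41 in limma-voom, −1.26 with the cardiomyocyte covariate, −0.50 without the libraries that stand apart and −1.45 without type 1 replicate 4. In the same order Ighg2b was −0.72, −0.51, −1.12, −0.79 and −1.96, and Cyp2e1 was −0.60 with the covariate and −0.59 without replicate 4, where Car3 was −0.07 with the covariate. The highest values with 1 library left out were 5.82 for Igkv12-89 and 5.6 for Ighg2b (without non-diabetic replicate 4) and 6.22 for Cyp2e1 (without non-diabetic replicate 5). In type 1 against type 2 at day 7 Ighg2b was −0.49 both without the libraries that stand apart and without type 1 replicate 4, and 7.31 at most (without type 2 replicate 8). In type 2 at day 28 Igkv16-104 was −0.13 and Ighv1-39 −0.03 in both such fits (type 2 replicate 4), and Ighv1-39 was −0.11 in DESeq2, −0.31 in limma-voom and −0.08 with the covariate. The highest were 5.32 for Igkv16-104 and 3.98 for Ighv1-39, without non-diabetic replicates 8 and 11. Over time in non-diabetic tissue the cardiomyocyte covariate turned the medians of cardiac stress genes (−0.045) and neutrophil markers (0.21), and Napsa (0.41), Mrc1 (0.19), S100a8 (0.62) and Myh6 (−0.78), itself one of the markers.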

Other observations

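The test of an earlier stage of healing was chosen after the data were seen, and its threshold was tightened after a related value had been seen.

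Further groups changed with time in non-diabetic tissue, with day, project and makeup not separable. All 13 mitochondrial-DNA-encoded genes rose (median 2.18, fry adjusted p = 2.54e-10, adjusted p = 0.375 with an estimated correlation), with mt-Co3, a subunit of the last enzyme of respiration, at 3.43. Ketone body genes rose in 6 of 7 (median 1.55, fry adjusted p = 8.66e-16, adjusted p = 0.265 with an estimated correlation), with Oxct1 at 1.63. Lymphatic endothelial markers rose in 6 of 7 (median 1.72, fry adjusted p = 2.78e-12, adjusted p = 0.312 with an estimated correlation), with the chemokine Ccl21a at 3.42, Mmrn1 at 2.17 and Reln at 1.72. Mesothelial markers rose in 9 of 10 (median 2.15, fry adjusted p = 0.00703, adjusted p = 0.778 with an estimated correlation), with Upk3b at 3.39 and Krt19 at 2.79. Counts were the same over each of these lists alone.

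Lipid handling and LXR target genes fell in 14 of 19 and rose in 3 (median −1.32, fry adjusted p = 1.63e-20, adjusted p = 0.265 with an estimated correlation), with Abca1 at −1.86, Fabp5 at −1.85 and Lipa at −1.32. Cytokines and chemokines fell in 15 of 22 and rose in 1 (median −0.93, fry adjusted p = 0.000114, adjusted p = 0.697 with an estimated correlation), with Ccl3 at −2.27 and Ccl2 at −1.19, while Il1b was at 0.01 and did not pass. Interferon-stimulated genes fell in 15 of 25 and rose in 1 (median −0.41, fry adjusted p = 0.0188, adjusted p = 0.886 with an estimated correlation), with Oas3 at −1.66 and Mx1 at −1.06. Hypoxia and angiogenesis genes rose in 8 of 17 and fell in 1 (median 0.22, fry adjusted p = 2.58e-08, adjusted p = 0.435 with an estimated correlation), with Vegfa at 1.94 and the oxygen sensors Egln3 and Egln1 at 1.62 and 1.58. Counts over each of these lists alone were the same.

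A hypothesis is that type 1 infarcts may be at an earlier stage of healing at day 7. If so, and if genes moved one way throughout healing, the type 1 effect at day 7 would run against the change of non-diabetic tissue with time. Across 20421 genes, which are not independent replicates, and with non-diabetic day 7 libraries split so that none entered both effects, the mean Spearman correlation was −0.26 over 70 splits (from −0.417 to −0.049), and −0.189 for type 2 (from −0.386 to 0.09). Lists went both ways: all 30 cell cycle genes and 15 macrophage markers fell with time and 28 and 8 were higher in type 1 at day 7, while all 18 collagens and 10 of 12 myofibroblast markers fell with time and 11 of 18 and 6 of 12 were lower in type 1. With shared controls the correlations were −0.208 and −0.117, and with cardiomyocyte markers as a covariate, over 18156 genes, −0.03 and −0.07, so for type 1 an earlier stage and a smaller share of cardiomyocytes cannot be told apart, nor can time and project.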
